A study of Drosophila melanogaster with 6 samples.

How the data were processed

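Brains of 15-day-old w1118 flies were dissected by hand and frozen, and RNA was extracted with Trizol, per the labels' protocols. Libraries were made from 100 ng of total RNA with a stranded mRNA kit, 3 from flies on normal food and 3 from flies on food with spermidine. HTSeq, Cufflinks and DESeq are named in the submitters' processing notes, without versions or roles, and the aligner is not given in the sources used here. The gene models are Ensembl build 82 per the file headers, and all coordinates are those of the table. Of 17141 genes with a position in both that table and the Ensembl annotation of the current fly assembly, 99.8% lay at the same place within 2000 bases.

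The deposited FPKM value of each gene and library comes with a status given by the authors' software. The authors also deposited mean normalized counts per group, which are a signal with no value per library, a signed fold change that is a score here because it has no values between -1 and 1, and an unadjusted p-value. Of the 11 deposited sheets, 1 holds all 17483 genes and was used, and the others were subsets of it or empty. Current symbols were found for 17180 gene identifiers, and the table's own symbol was kept for the other 303. The FPKM sums ranged from 615229 to 720639 per library, of which the stem loop mir-4940 alone took between 14.2% and 25.9%, because FPKM overstates very short genes. Genes whose status was not OK in any library (215 genes) were left out, since a failed estimate is listed at 0. The 31 genes with a failed estimate in at least 1 library include abundant ones such as Hsc70-4, cpx and Cam.

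The test had been fixed before the data were examined as a count test where counts were deposited and otherwise as limma on log values. Without counts per library, limma 3.58.1 in R 4.3.3 was run with an intensity trend on log2(FPKM + 1), with no covariates, two-sided, and Benjamini-Hochberg adjustment with a threshold of 0.05. Fold changes are on that scale, which understates changes of genes of low FPKM. The filter, an FPKM of at least 0.5 in at least 3 of the 6 libraries, was chosen after the files had been seen, and it left 10366 genes. Values printed as mean ± SD are FPKM over 3 libraries. An exact permutation test of a single gene with 3 against 3 libraries cannot give a p under 0.1. The table used here gives no depth per library, so no counting intervals are given.

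The 28 gene lists and the rule for named genes were fixed before the data were examined. The lists cover polyamine and hypusination genes, autophagy, lysosome and V-ATPase, respiratory chain (nuclear and mitochondrially encoded), cytosolic and mitochondrial ribosomal proteins, glycolysis, proteasome, heat shock, endoplasmic reticulum stress, detoxification, immunity, insulin and TOR signalling, synapse, neurotransmitters, neuropeptides, clock, activity-regulated genes, and markers of glia, photoreceptors, fat body, muscle, haemocytes, cuticle, gut, odorant-binding proteins and sex. Named genes are the 10 largest rises and the 10 largest falls among genes past the threshold with a mean FPKM of at least 1 and no overlap between the groups, up to 4 members of each list with the smallest p, all measured polyamine and hypusination genes, and genes past the threshold here whose deposited fold change has the opposite sign at an unadjusted p under 0.05. Other genes named (apolpp, Lsp2, ninaE, Obp56d, Obp57b and those in the closing section) were chosen after their values were seen, and 1 gene that the rule takes is not reported here. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation beside it, and with fry. The fry test was run for a common direction and for mixed directions.

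The model was tested on simulated libraries of the 10366 genes, in which 50 genes each were changed by 1.25, 1.5, 2 and 4 times. It recovered 36%, 76%, 92% and 88% of them and called 8 unchanged genes. The changed genes all had a mean above 2 on the log2(FPKM + 1) scale, and noise was drawn separately for each gene. Recovery of genes of low FPKM and the effect of noise shared between genes were therefore not tested. Term enrichment and matched draws were tested on 20 simulated sets each. All 20 planted terms and all 20 sets shifted by -0.2 on the log2 scale were found, and none of 20 unshifted sets was, while 2 terms passed over 20 random gene sets. Enrichment of the terms listed in the table used Fisher's exact test in scipy against the tested genes with at least 1 term. Alternatives covered the scaling, the filter, the pseudocount, the threshold, the replicate number as a block, the trend, each library left out, and the authors' p-values. The count-based alternatives that had been planned were not run.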

Results

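Messenger RNA from dissected brains of 15-day-old flies of w1118, a white-eyed laboratory strain of Drosophila melanogaster, was sequenced in 6 libraries. Flies of 3 libraries were reared on normal food and flies of the other 3 on the same food with spermidine, a polyamine found in all cells. The labels give neither the dose nor the sex of the flies. The deposited table holds an FPKM value for each of 17483 genes in each library, together with the authors' mean normalized count per group. Those means summed to 48052547 normalized reads on normal food and 47904049 on spermidine food. Read counts per library were not part of the table, and the worth of 1 read in genes of very low expression put the relative depth of the libraries between 0.804 for spermidine food replicate 3 and 1 for normal food replicate 1. The labels call the libraries replicates without saying that they came from separate cultures, so the p-values measure the spread between these 6 libraries, which may be technical.

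The design implies 1 comparison, spermidine food against normal food, which asks how supplementation changes the transcriptome of the ageing brain. Genes of the yolk proteins, of secreted immune peptides and of detoxifying enzymes were among those that rose. The RNA of fit, a secreted protein of the fat body that responds to feeding, went from 60.9 ± 3.37 FPKM on normal food to 484 ± 62.5 on spermidine food (SD, n = 3 each), a log2 fold change of 2.97 ± 0.10 (SE). That of Yp2, a yolk protein, went from 690 ± 32.2 to 3888 ± 276 FPKM (SD, n = 3 each). Few falls reached 2-fold, and among genes with well-described products the falls included RpL38, a protein of the large ribosomal subunit. Of the 10366 genes tested with limma on log2(FPKM + 1), 491 passed a Benjamini-Hochberg adjusted p of 0.05, with 333 higher and 158 lower on spermidine food, so 67.8% of the calls were higher. At least a 2-fold change was reached by 111 of the higher and 13 of the lower genes. The count depended on single libraries, since 55 genes passed without spermidine food replicate 3, and 177 without spermidine food replicate 1. Of the 45 calls among genes taken by the rule for named genes, 36 ended without the former (that of Yp1 at an adjusted p of 0.054 and that of SpdS, spermidine synthase, at 0.0784) and 25 without the latter. Those of fit, Yp2, Yp3, Obp99a, Cyp4e2, Cyp6w1, scaRNA:PsiU5-44 and snoRNA:Psi28S-1175b, 8 in all, held without each library in turn. The call of snoRNA:Psi28S-1175b rests on almost no reads, with mean normalized counts of 1.95 on normal food and 0.32 on spermidine food. Its small p is therefore no sign of a sound call. The p-values in the authors' deposited table, adjusted over the same genes, gave 1752 genes, of which 850 were higher and 902 lower. In those values roX1, Oda, Obp56d, Atg8a and Atg101 are lower and apolpp, Ilp2, Prosbeta2 and COX7C higher past the threshold, which none of them passed in limma, while CG6685 and mRpL34 do not pass.

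**Figure D1:**
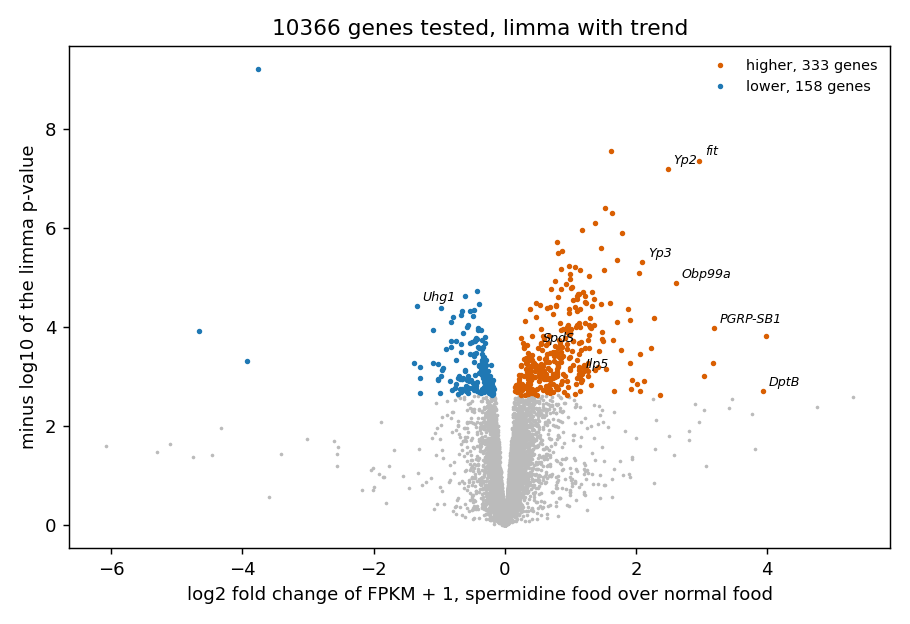
Each point is 1 of the 10366 genes tested, with its log2 fold change of FPKM + 1 (spermidine food over normal food) on the x axis and minus log10 of its limma p-value on the y axis. Of the 333 higher genes 111 changed at least 2-fold, against 13 of the 158 lower genes, and fit and Yp2 stand at the top right.

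Of the fat body list, 9 members were measured and 4 rose, none fell and 5 did not pass the test (7 rose when adjusted over the list alone). The 4 were fit and the 3 yolk protein genes, which lie on the X chromosome. Yp2 (FBgn0005391, X, 10050951 to 10052636) rose by 2.49 ± 0.09 on the log2 scale (limma, adjusted p = 0.00017). Yp3 (FBgn0004047, X, 13759546 to 13761547) went from 977 ± 156 to 4162 ± 405 FPKM, and Yp1 from 369 ± 94.2 to 1340 ± 142 FPKM (SD, n = 3 each). The gene fit (FBgn0038914) lies on chromosome arm 3R from 21883924 to 21884454 and had an adjusted p of 0.00015 in limma. Among the members that did not pass, Lsp2, a larval storage protein, had 1.22, 2.67 and 0.814 FPKM in the normal food libraries and 319, 14.51 and 184 in the spermidine food libraries (limma, adjusted p = 0.052). The lipid carrier apolpp had 133 FPKM on normal food and 211 on spermidine food (limma, adjusted p = 0.093). The list as a whole was higher by camera with a preset correlation (adjusted p = 5.06e-08), with a median log2 fold change of 2.10, but not with an estimated correlation (adjusted p = 0.437). In the list of dosage and yolk genes that reads the sex of the flies, 3 of 4 measured members rose, all of them yolk protein genes, and roX1, a noncoding RNA of male dosage compensation, had 8.89 ± 0.79 FPKM on normal food and 6.68 ± 0.41 on spermidine food (limma, adjusted p = 0.056). Adjusted over the list alone, roX1 fell. That list was higher by camera (adjusted p = 0.0058, and adjusted p = 0.496 with an estimated correlation).

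Genes of humoral immunity formed the list with the smallest camera p. Of 33 measured members, 7 rose, none fell and 26 did not pass the test, and all 33 had a higher mean on spermidine food. Adjusted over the list alone, 23 rose. DptB (FBgn0034407, 2R, 18867391 to 18867895), which encodes the antibacterial peptide diptericin B, went from 10.96 ± 3.48 to 248 ± 197 FPKM. Mtk, the gene of the antifungal and antibacterial peptide metchnikowin, went from 74.5 ± 26.7 to 727 ± 409 FPKM, and PGRP-SB1, a peptidoglycan-cleaving protein, from 15.5 ± 4.09 to 158 ± 72.1 FPKM (SD, n = 3 each). CecC, a cecropin, rose from 1.07 to 11.4 FPKM (limma, adjusted p = 0.049). The rises were uneven between the spermidine food libraries, with DptB at 444, 49.6 and 250 FPKM in replicates 1, 2 and 3. Smaller rises were found in Tep2, a thioester protein, with a log2 fold change of 0.79 ± 0.13 (SE), and in PGRP-LB, which degrades peptidoglycan, with 0.55 ± 0.09 (SE). Camera gave an adjusted p of 1.42e-11 for the list, and an adjusted p of 0.496 with an estimated correlation. The mean of the fat body list moved in the same libraries, from between 6.10 and 6.18 on the log2(FPKM + 1) scale on normal food to 8.56, 7.52 and 8.41 in spermidine food replicates 1, 2 and 3. The dip in replicate 2 was far larger in Lsp2 (319, 14.51 and 184 FPKM) than in fit (555, 435 and 464 FPKM). Of the other fat body genes past the threshold, Yp3 (4401, 3695 and 4391 FPKM) and Yp1 (1468, 1188 and 1364 FPKM) were, like fit, lowest in replicate 2. The dips of fit, Yp3 and Yp1 were small beside that of DptB. Yp2 was not lowest there (3570, 4061 and 4033 FPKM). Of 8 haemocyte genes measured, 1 rose, the scavenger receptor gene Sr-CI, from 4.28 ± 0.69 to 7.85 ± 0.64 FPKM (SD, n = 3 each), and 5 rose when adjusted over the list alone (camera adjusted p = 0.013, and adjusted p = 0.496 with an estimated correlation).

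**Figure D2:**
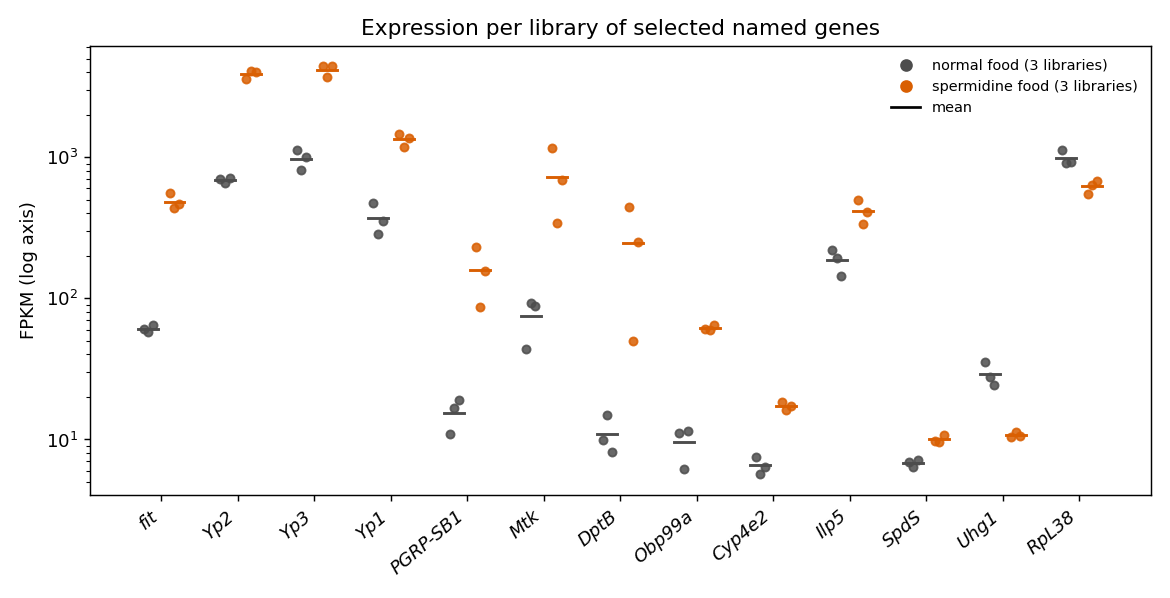
FPKM of 13 genes on a log axis, with 1 point per library (3 on normal food in grey, 3 on spermidine food in orange) and a bar at each group's mean. The points of the 2 foods do not overlap for any gene shown, and the spread on spermidine food is widest for DptB, from 49.6 to 444 FPKM.

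Of 31 measured genes of the antioxidant and detoxification list, 9 rose, none fell and 22 did not pass the test, while 18 rose when adjusted over the list alone. Cyp4e2 (FBgn0014469, 2R, 8444560 to 8447164), a cytochrome P450, went from 6.542 ± 0.93 to 17.3 ± 1.06 FPKM (SD, n = 3 each). Among the other cytochromes P450, Cyp6w1 rose by 0.71 ± 0.06 and Cyp6g1, known for its part in insecticide resistance, by 0.73 ± 0.08 on the log2 scale (SE). GstE1, a glutathione transferase, went from 70.5 ± 5.10 to 111 ± 5.67 FPKM (SD, n = 3 each). The list was higher by camera (adjusted p = 2.08e-08, and adjusted p = 0.496 with an estimated correlation). Cyp4g1, a P450 of hydrocarbon synthesis in oenocytes that was not on the list, rose from 6.32 ± 4.59 to 49.9 ± 8.32 FPKM, and Fad2, a desaturase of female pheromone synthesis, from 0.55 ± 0.48 to 6.35 ± 1.32 FPKM (SD, n = 3 each). Of 26 odorant-binding protein genes measured, 4 rose and none fell, and adjusted over the list alone 4 rose and 2 fell (Obp56d, from 17.01 ± 3.91 to 7.73 ± 2.37 FPKM, SD, n = 3 each, and Obp57b, from 0.69 to 0.31 FPKM). Obp99a had the largest change, from 9.57 ± 2.96 to 61.4 ± 2.63 FPKM, and Obp99c went from 131 ± 21.6 to 292 ± 39.1 FPKM (SD, n = 3 each). Obp83cd and Obp83ef rose by 1.24 ± 0.12 and 1.10 ± 0.12 on the log2 scale (SE), and because the annotated spans of these neighbours overlap their values may share reads. The odorant-binding list did not pass camera (adjusted p = 0.071), but it was higher under median-ratio scaling (adjusted p = 0.023), without normal food replicate 1 (adjusted p = 0.033) and without spermidine food replicate 2 (adjusted p = 0.045).

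The lists of the polyamine pathway and of autophagy, the process that spermidine is best known to induce, did not move in a common direction. In fry's mixed test, which asks for changes in either direction within the list alone, both passed (adjusted p = 0.00076 and 0.0097). Of 9 measured polyamine and hypusination genes, 1 rose and 8 did not pass the test (camera adjusted p = 0.909). The gene that rose was SpdS (FBgn0037723, 3R, 9631641 to 9633673), which encodes spermidine synthase, from 6.80 ± 0.43 to 10.03 ± 0.61 FPKM (SD, n = 3 each; limma, adjusted p = 0.017). Ornithine decarboxylase, the entry enzyme of the pathway, had close means for Odc1 (7.21 and 7.20 FPKM) and for Odc2 (0.97 and 1.25 FPKM), and its inhibitor Oda had 786 FPKM on normal food and 715 on spermidine food (limma, adjusted p = 0.285). SamDC had 21.8 and 20.1 FPKM, and Sms, spermine synthase, had 63.4 and 60.3 FPKM. eIF-5A, the translation factor that carries the hypusine made from spermidine, had 250 ± 25.8 FPKM on normal food and 281 ± 16.64 on spermidine food (SD, n = 3 each; limma, adjusted p = 0.323). The hypusination enzymes Dhps and nero had log2 fold changes of 0.06 ± 0.05 and -0.01 ± 0.08 (SE). Of 27 measured autophagy genes none passed the test (limma over all genes tested, in which 2183 genes had an unadjusted p under 0.05), and none did when adjusted over the list alone. In the authors' p-values, adjusted over the same genes, 3 were lower, Mitf (deposited fold change -1.2), Atg101 (-1.15) and Atg8a (-1.1), and none higher. Their median log2 fold change was -0.01 (camera adjusted p = 0.268). Atg8a, the ubiquitin-like protein of the autophagosome membrane, had 309 ± 18.7 FPKM on normal food and 283 ± 6.75 on spermidine food (SD, n = 3 each), and Atg101 had 47.8 and 42.5 FPKM (limma, adjusted p = 0.09). The lysosome and V-ATPase list (24 measured, median 0.01, camera adjusted p = 0.512) also had no member past the threshold in limma, against 4 higher and 1 lower in the authors' values.

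**Figure D3:**
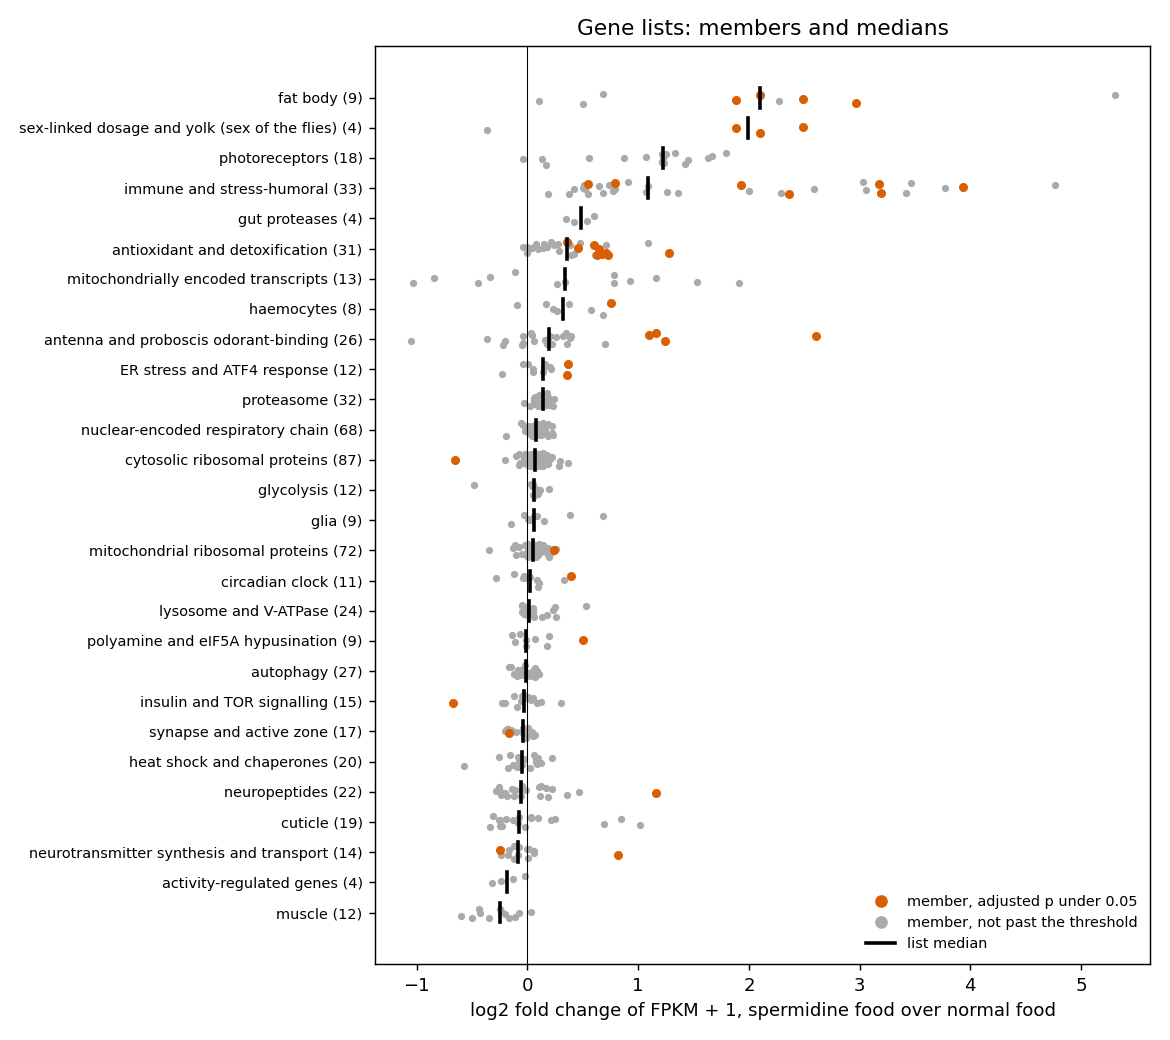
Log2 fold change of FPKM + 1 (x axis, spermidine food over normal food) of the members of the 28 gene lists (y axis, number of measured members in brackets). Orange points passed an adjusted p of 0.05, grey points did not, and the black bar is the list median, which is highest for the fat body list at 2.10 and lowest for the muscle list at -0.24.

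By camera at the preset correlation, the lists of the proteasome, the nuclear respiratory chain and cytosolic ribosomal proteins were higher by small steps. Their estimated correlations were 0.465, 0.488 and 0.523, so the members of each list moved together between libraries. None of these lists passed fry in a common direction (adjusted p = 0.089, 0.34 and 0.529). In fry's mixed test the proteasome list passed (adjusted p = 0.018) and the others did not. Means of the respiratory chain list overlapped, at 7.86, 7.74 and 7.81 on normal food and 7.83, 7.91 and 7.93 on spermidine food (log2(FPKM + 1)). All but 1 of 32 proteasome genes had a higher mean on spermidine food, with a median log2 fold change of 0.14. None passed the test over all genes, and 14 rose when adjusted over the list alone, among them Prosbeta2 with 46.1 ± 1.48 and 52.5 ± 1.31 FPKM (SD, n = 3 each). Camera gave an adjusted p of 4.4e-07, and an adjusted p of 0.53 with an estimated correlation. Of 68 nuclear genes of the respiratory chain, 63 had a higher mean, with a median of 0.08 and none past the threshold (camera adjusted p = 0.00094, and adjusted p = 0.822 with an estimated correlation). COX7C had the smallest p of that list, with 408 ± 15.0 and 477 ± 8.97 FPKM (SD, n = 3 each). Among 87 cytosolic ribosomal protein genes, 1 fell, none rose and 74 had a higher mean (camera adjusted p = 0.031, and adjusted p = 0.863 with an estimated correlation). That list did not pass camera without normal food replicate 2 or 3 (adjusted p = 0.251 and 0.134) or without spermidine food replicate 2 or 3 (adjusted p = 0.284 and 0.124). The gene that fell was RpL38 (FBgn0040007, 2R, 4515388 to 4516458), from 984 ± 120 to 622 ± 66.5 FPKM (SD, n = 3 each). RpL38 lies near the centromere of 2R, where other genes fell too. Of 12 endoplasmic reticulum stress genes, the chaperone gene Gp93 and the disulfide isomerase gene Pdi rose, with 0.36 ± 0.06 and 0.36 ± 0.07 on the log2 scale (SE), and 7 rose when adjusted over the list alone (camera adjusted p = 0.013, and adjusted p = 0.496 with an estimated correlation). Mitochondrial ribosomal proteins (72 measured, 1 rose, mRpL34, camera adjusted p = 0.066), mitochondrially encoded transcripts (13 measured, none past the threshold, camera adjusted p = 0.804), glycolysis (12 measured, none past it, camera adjusted p = 0.393) and heat shock genes (20 measured, none past it, camera adjusted p = 0.251) did not move in a common direction. Of these, only the heat shock list passed fry's mixed test (adjusted p = 0.0021). Mitochondrial ribosomal proteins did pass camera without normal food replicate 1 (adjusted p = 0.0026) or spermidine food replicate 3 (adjusted p = 0.0086), and mitochondrially encoded transcripts without the latter (higher, adjusted p = 0.016).

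Of 17 synapse and active zone genes, 1 fell and none rose, and 13 had a lower mean on spermidine food. The one that fell was Syn, a protein of synaptic vesicles, from 158 ± 1.81 to 140 ± 2.98 FPKM (SD, n = 3 each), and 4 fell when adjusted over the list alone. Camera gave the list an adjusted p of 0.011, an adjusted p of 0.496 with an estimated correlation and an adjusted p of 0.058 without normal food replicate 2. Of 14 genes of neurotransmitter synthesis and transport, Gad1, which makes GABA, fell by 0.25 on the log2 scale and Hn, the phenylalanine hydroxylase gene, rose by 0.82 ± 0.11 on the log2 scale (SE). That list was lower by camera (adjusted p = 0.023, and adjusted p = 0.496 with an estimated correlation), and did not pass without normal food replicate 2 (adjusted p = 0.056), spermidine food replicate 1 (adjusted p = 0.055) or spermidine food replicate 2 (adjusted p = 0.082). When adjusted over the list alone, 3 of its genes fell and 1 rose. The 4 activity-regulated genes had lower means without passing the test, and 2 fell when adjusted over the list alone (camera adjusted p = 0.017, adjusted p = 0.505 with an estimated correlation, and 0.056 and 0.065 without normal food replicate 2 and 3). Of 22 neuropeptide genes, 1 rose, Ilp5, an insulin-like peptide of brain neurosecretory cells, from 186 ± 37.3 to 414 ± 81.7 FPKM (SD, n = 3 each), while Ilp2, from the same cells, had 604 ± 65.0 and 831 ± 57.2 FPKM (SD, n = 3 each; limma, adjusted p = 0.051). The neuropeptide list did not pass camera (adjusted p = 0.574), and 4 of its genes rose when adjusted over the list alone. The list of 15 measured insulin and TOR signalling genes did not pass camera (adjusted p = 0.103) but was lower without normal food replicate 1 (adjusted p = 0.02). Of 11 clock genes, 1 rose, Clk, from 4.82 ± 0.21 to 6.65 ± 0.42 FPKM (SD, n = 3 each; list camera adjusted p = 0.525), and 2 rose when adjusted over the list alone. No glial gene of 9 passed (camera adjusted p = 0.615), and 1 rose when adjusted over the list alone.

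Markers of other tissues differed between the libraries, also within a food. The photoreceptor list had a median log2 fold change of 1.22 with no member of 18 past the threshold (camera adjusted p = 0.017, adjusted p = 0.822 with an estimated correlation, 0.074 without normal food replicate 1 and 0.092 without spermidine food replicate 1). The rhodopsin gene ninaE had 776 FPKM in normal food replicate 1 against 5212 and 3385 in replicates 2 and 3, and between 4633 and 6715 on spermidine food. The muscle list was highest in the same library, at a mean of 2.91 on the log2(FPKM + 1) scale against 1.46 and 2.11 in the other normal food libraries and between 1.30 and 2.38 on spermidine food (median log2 fold change -0.24, none of 12 past the threshold, camera adjusted p = 0.093, and lower at an adjusted p of 0.004 without normal food replicate 2 and of 0.015 without spermidine food replicate 2). Cuticle genes (19 measured, none past the threshold, camera adjusted p = 0.504) and gut protease genes (4 measured, none past it, camera adjusted p = 0.512) did not move as lists. Without normal food replicate 1, 313 genes passed the test.

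Most of the largest falls were in short or noncoding RNAs. Uhg1, a host gene of small nucleolar RNAs on chromosome arm 2R from 17699097 to 17703344, fell from 29.1 ± 5.68 to 10.7 ± 0.46 FPKM (SD, n = 3 each), a log2 fold change of -1.34 ± 0.13 (SE). The small nucleolar RNA snoRNA:SC35-b fell from 41.1 ± 5.68 to 2.39 ± 2.09 FPKM (SD, n = 3 each), and scaRNA:PsiU5-44 from 144 ± 22.1 to 66.2 ± 7.83 FPKM (SD, n = 3 each). snoRNA:Psi28S-1175b and snoRNA:Psi28S-1192c were listed at 0 in the 3 spermidine food libraries, and snoRNA:Psi18S-1854b was listed at 0 in the 3 normal food libraries. The authors' mean normalized counts of these 3 genes were 1.95 and 0.32, 12.13 and 5.07, and 1.92 and 3.13 on normal and spermidine food, with deposited fold changes of -1.07, -1.17 and 1.04. CG33217 and the noncoding lncRNA:CR43956, CR41454 and asRNA:CR45612 fell as well, with log2 fold changes between -1.39 and -1.10, and CG6685 had -1.02 ± 0.18 (SE). CG33217 and CR41454 are neighbours near the centromere of 3L. lncRNA:CR43956 lies on chromosome 4 within the span of the gene anne, which also fell. Both places are among those where other genes fell too, so these falls are not separate from the fall by position described below. CG6685 overlaps another annotated gene, and its mean normalized counts were 391 on normal food and 369 on spermidine food (deposited fold change -1.05). The authors' counts thus show hardly any fall of CG6685. CR41454 and asRNA:CR45612 have fold changes of 1 and 1.01 in the authors' deposited table, where they rest on no or almost no counts (mean normalized counts 0 and 0 for CR41454, and 0 and 0.32 for asRNA:CR45612). The 2 genes past the threshold here whose deposited fold change has the opposite sign at an unadjusted p under 0.05 were CG33655 and asRNA:CR45141, with log2 fold changes of 0.31 ± 0.03 and 0.18 ± 0.04 (SE) against deposited fold changes of -1.25 and -1.24. The authors' p-values of these 2 genes, adjusted over the same genes, were 0.161 and 0.071, so neither is past the threshold in the authors' values.

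Along the chromosomes, the medians of most 1 Mb bins lay near the median over all genes of 0.02 on the log2 scale, while those of chromosome 4 and of single bins of 5 to 19 genes near the centromeres of 2R (2 and 4 Mb), 3L (23 and 24 Mb) and 3R (3 Mb) were lower, the latter between -0.336 and -0.274. The bins still nearer the centromere stood at -0.078 on 2R (1 Mb) and at -0.062 and -0.011 on 3L (25 and 27 Mb), and the next bin of 3R, of 85 genes, at 0.006. Bins at the ends of 2L (22 and 23 Mb) and X (23 Mb) stood at -0.096, -0.057 and -0.072, and that at the far end of 2R (25 Mb) at -0.085. On chromosome 4, 101 genes were tested, and their median log2 fold change was -0.18.

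**Figure D4:**
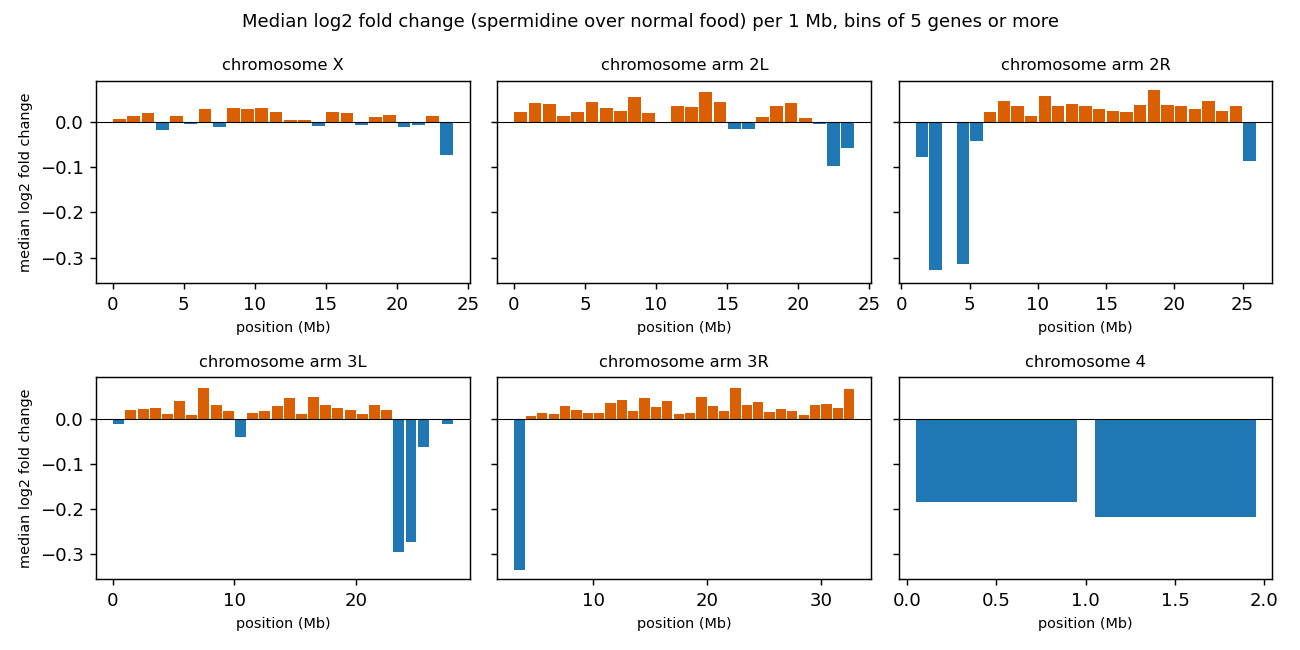
Median log2 fold change of FPKM + 1 (y axis, spermidine food over normal food) of the tested genes in bins of 1 Mb along each chromosome arm (x axis, position in Mb), for bins of at least 5 genes. The bins of chromosome 4 stand at -0.18 and -0.22, and those at 2 and 4 Mb of 2R at -0.33 and -0.31.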

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

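The gene Hsc70-4, a constitutive heat shock cognate, had no usable FPKM because the estimate failed in 4 of the 6 libraries, and it was therefore left out of the test. In the authors' deposited table its mean normalized counts were 62011 on normal food and 72788 on spermidine food, a fold change of 1.17 with an unadjusted p of 0.000139. It was picked out because it is a signal above the normal food level in data that the comparison did not use. Of the other 30 genes with a failed estimate, cpx, the complexin of synaptic vesicle release, has a deposited fold change of -1.34, from 135222 to 99723 mean normalized counts.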

How the results depend on the processing

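The alternatives that use the authors' p-values, a pseudocount of 0.1 with the same filter, no trend, fewer genes or 2 libraries per group were chosen after seeing the data. Of the 491 genes (333 higher and 158 lower), the count stayed within 1.5 times under median-ratio scaling (580), a mean of at least 50 normalized counts (499), a pseudocount of 0.1 (485), without the fat body, haemocyte, immune and yolk genes (483) and without the intensity trend (426). Leaving out the fat body, haemocyte, immune and yolk genes kept 10315 genes in the test and 479 of the 491 calls. That took out too few genes to show whether the count rests on such tissues. Without a filter on low values 261 of 15662 genes passed (186 higher, 75 lower), and with a pseudocount of 0.1 as well 332 (231 higher, 101 lower), and the cause was not tested. At an adjusted p under 0.01, 76 passed (64 higher, 12 lower), and with at least a 1.5-fold change 266 (217 higher, 49 lower). Without single libraries the counts lay between 55 and 322, with 49 to 239 higher and 6 to 94 lower, and the cause was not tested beyond the smaller number of libraries. They were 313, 248 and 270 without normal food replicates 1, 2 and 3, and 177, 322 and 55 without spermidine food replicates 1, 2 and 3, and of 45 named calls 14, 20 and 16, and 25, 12 and 36 ended. Without the library of each group farthest from its group on the first component, 282 passed (217 higher, 65 lower). The authors' deposited p-values, adjusted, gave 1752 genes (850 higher, 902 lower), of which 418 are among the 491, and of 131 named genes 50 gained a call there and 5 lost it. In those values CR41454 (log2 0) and asRNA:CR45612 (0.0144) have almost no counts, and CG33655 (-0.32) and asRNA:CR45141 (-0.31) have the other sign, not past the threshold, and the cause was not tested. Of the 28 lists, 13 moved by camera, 0 with an estimated correlation and 4 by fry in a common direction, and between 10 and 15 without single libraries. With the replicate number as a block, 257 genes passed (183 higher, 74 lower), 214 of them among the 491, 17 named calls ended, and 13 lists moved, with the odorant-binding list gained (adjusted p = 0.0487) and the cytosolic ribosomal list lost (adjusted p = 0.0753). The numbers did not pair the samples, as deviations of same-numbered libraries correlated at -0.05, -0.10 and 0.02 and of the 6 libraries 1, spermidine food replicate 3, correlated best with its own number. The planned count tests and voom were not run because the table holds no counts per library.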

Other observations

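The tests of matched genes, noncoding genes and roX1 on chromosome 4 and the comparison of fit with Yp1 were chosen only after the result was seen. Terms of gene function were tested for enrichment with Fisher's exact test among the 289 genes that rose and carry a term, against 8462 tested genes with a term, and 25 of 987 terms passed a Benjamini-Hochberg adjusted p of 0.05. Of 39 genes with serine-type endopeptidase inhibitor activity, 12 rose, an enrichment of 9.01 over the background, including nec, Spn42Da and Spn88Eb, which are serpins. Of 96 genes of iron ion binding, 22 rose, most of them cytochromes P450. Of 64 metallopeptidase genes, 14 rose, most of them neprilysin-like. Among the genes that fell, 1 term passed, signal transduction, with 12 of 170 genes. Its members include Eph and RhoGAP102A, which lie on chromosome 4, and the positions of all members were not tested. The term can therefore not be told apart from the fall by position described below.

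Of 7 tested host genes of small nucleolar RNAs, 4 fell (Uhg1, Uhg3, Uhg4 and Uhg5), with log2 fold changes from -1.34 ± 0.13 for Uhg1 to -0.35 ± 0.05 (SE) for Uhg4. The 77 small nucleolar RNA genes tested had a median of 0.03. The very low oenocyte and pheromone genes eloF and FASN2 also rose, from 0.12 to 1.40 and from 0.16 to 0.85 FPKM. CG4210, whose annotation in the table is N-acetyltransferase activity and which overlaps another gene, has a fold change of -1.73 in the authors' deposited table and a log2 fold change of -0.29 ± 0.18 (SE) in FPKM.

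Genes of chromosome 4 and next to some centromeres were lower on spermidine food. On chromosome 4, 34 of 101 tested genes fell and none rose, against 86 of 9965 elsewhere (0.86%), an odds ratio of 58.3 (Fisher's exact test, two-sided p = 1.17e-41, across genes that are not independent replicates). Examples are MED26, a Mediator subunit, from 46.5 ± 4.63 to 29.6 ± 1.15 FPKM, and the ephrin receptor gene Eph, from 108 ± 4.90 to 84.2 ± 1.69 FPKM (SD, n = 3 each). Near the centromeres, 14 of 42 genes of 2R and 15 of 46 of 3L fell, against 3 of 29 on 2L, 4 of 91 on 3R (median -0.005) and none of 43 on the X, with Haspin, the histone kinase, from 25.5 ± 3.52 to 12.5 ± 0.45 FPKM and the cohesin loader Nipped-B from 59.4 ± 7.56 to 35.1 ± 1.98 FPKM (SD, n = 3 each). The regions were set after seeing the data, as 5 Mb on 2R, 3L and 3R and 1.5 Mb on 2L and X, and with 5 Mb on each arm the median of the 805 genes was 0. Over all genes tested, 6 were called lower without spermidine food replicate 3 and 41 without spermidine food replicate 1. The counts of falls on chromosome 4, 2R and 3L therefore do not hold without spermidine food replicate 3.

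Several explanations were set against the fall on chromosome 4, where the coding genes had a median log2 fold change of -0.18 and kept one between -0.19 and -0.14 without each library in turn. Coding genes elsewhere matched on gene span, exon length and FPKM had a median of 0.011, and none of 10000 draws went as low as chromosome 4. These values argue against gene structure as the whole cause. Noncoding genes elsewhere had a median of -0.009, and 2.72% of them fell, against 0.69% of coding genes elsewhere. The scale understates changes of genes of low FPKM, and nuclear RNAs were not tested as a set. A lower yield of nuclear or noncoding RNA therefore stays open. With the centromere-proximal genes included, the median was -0.069, and again none of 10000 draws went as low. The gap to matched genes (median 0.014) was 0.083, however, under the bound of 0.1 set beforehand. By that bound gene structure stays open for those genes, and chromosome 4 was taken alone after that result was seen. A smaller share of males, which carry the heterochromatic Y chromosome, stays open. The log2 fold change of roX1, -0.36 ± 0.08 (SE), was larger in size than the median fall on chromosome 4. Single genes of chromosome 4 fell by more than roX1, such as MED26 with -0.63 ± 0.08 (SE), but they were picked for small p-values. An effect of spermidine on heterochromatic genes also stays open and was not tested further, and the largest difference between chromosome 4 and elsewhere in any other of the 10 splits of the libraries was 0.12 in size, against -0.208 in the real one.

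The rise of the yolk protein and fat body genes may have a source outside the brain. Unchanged fat body carried along in larger amounts, or a larger share of females, would raise Yp1, Yp2, Yp3 and fit by 1 common fold. The log2 fold change of fit exceeded that of Yp1 by 1.08 ± 0.20 (SE), beyond a t limit of 0.97 for the 6 pairs of these genes. Another source of any of these genes would also make their folds unequal, so both explanations stay open. Unequal folds had first been read against both, and that reading was changed after the result was seen. On the share of females, roX1 had a log2 fold change of -0.36 ± 0.08 (SE) and Fad2 and eloF of female pheromone synthesis rose, while the male-biased genes sxe2, to, Cyp4d21 and roX2, all of low expression, had deposited fold changes of 1.2, 1.03, -1.03 and -1.09 (unadjusted p = 0.106, 0.824, 0.709 and 0.38). Their mean normalized counts were 34.7 and 49.1, 49.7 and 52.8, 6.62 and 5.34, and 18.2 and 12.9 on normal and spermidine food. The deposited fold changes are smaller in size than the ratios of these means, so they do not show that roX2 was unchanged. By the rule set beforehand, a muscle list median under 0.1 was to count against carry-over of several tissues at once. That median was -0.24, but the muscle list varied more between libraries of 1 food than between foods. The rule was therefore not applied, and such carry-over stays open too. The cuticle and odorant-binding lists had medians of -0.08 and 0.19. A response of fat body cells to spermidine stays open as a hypothesis, untested here.

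The authors' counts and the FPKM disagreed by at least 0.5 on the log2 scale in 32 of 8849 genes with a mean of at least 50 normalized counts. Of those 32, 71.9% overlap another annotated gene, against 50.4% of the others, an odds ratio of 2.51 (Fisher's exact test, two-sided p = 0.0201), which is consistent with reads of overlapping genes being assigned differently by the programs. No biological explanation was tested for this pattern.

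For the count of genes changed, the real split of the 6 libraries gave 491 genes and the highest of the other splits gave 2. With 10 splits, of which 1 gave as many, the share cannot go under 0.1, so the splits are too few for a verdict.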
